A study of Paralichthys olivaceus with 16 samples.

How the data were processed

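RNA from 16 kidney samples of Japanese flounder (Paralichthys olivaceus) was labelled with Cy3 and hybridised to 16 custom Agilent arrays, 1 sample per array. Samples were grouped by the injection named in the labels: 4 received phosphate-buffered saline (PBS control), and 3 each received formalin-killed cells (FKC) of Edwardsiella tarda, Lactococcus garvieae, Streptococcus iniae or Vibrio anguillarum. The labels number the samples within each group but do not say whether each sample is 1 fish, so p-values measure the spread between these samples, which may be in part technical.

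The arrays were scanned with an Axon GenePix scanner and extracted with Agilent Feature Extraction 9.5, per the labels and the submitters' processing notes. Each deposited scanner file gives a processed intensity on a linear scale, which per the file headers is background-subtracted and detrended within the array, with a surrogate value for spots not above background. It also gives the mean intensity and background intensity of each spot, and marks for spots well above background, saturated or unusual against their surroundings (outlier marks). No scaling between arrays is recorded in these files. A second deposited table by the authors holds log2 values of the same arrays with scale, shift and centring unstated. Its 9928 rows carry no probe names. Matched by line number, differences between arrays correlated with those of the scanner files' log2 processed intensities at r = 0.995 to 0.998 for every array, whereas matching by feature number gave r between −0.02 and 0.02. That comparison settled the scale as log2, the direction as the same, and the centring as each row's median over the 16 arrays. How the authors shifted the arrays against each other stays unknown. Column medians of that table were 0.03, −0.08, −0.01 and 0.11 for controls 1 to 4. They were −0.01, 0.07 and 0.00 for E. tarda samples 1 to 3, and −0.04, 0.07 and 0.01 for L. garvieae samples 1 to 3. For S. iniae samples 1 to 3 they were 0.05, −0.05 and −0.09, and for V. anguillarum samples 1 to 3 −0.04, −0.00068 and −0.07.

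Each array held 10593 spots, of which 10057 were not controls and covered 9877 probes of 60 bases. Of these, 4727 are named for contigs, 4710 carry the same contig names with the prefix rev_, and 440 are named by 437 sequence accessions. None of the accessions or contig names matched the gene table used here (assembly ASM2471397v2), and 0 probes carry a description of a gene. Probes are therefore reported by the names in the files and by their sequences. All 25 gene lists fixed beforehand, the cell type marker lists among them, had 0 members on the array, so the planned list tests (camera and fry) and the comparison of cell type markers were not run. A total of 190 probes share their sequence with another probe.

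The log2 processed intensity was taken relative to each array's 75th percentile over all non-control spots. Control spots were left out, spots with an outlier mark were set to missing, saturated spots were kept, and the spots of 1 probe were averaged. Probes were kept when well above background on every array of at least 1 of the 5 groups, with at least 0.5 of a probe's spots required. This kept 6450 probes, of which 66 had an outlier mark on every array and 5451 were well above background on all 16. A linear model with 5 group means was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), which left 11 residual degrees of freedom. Moderated tests of both directions were adjusted per comparison by Benjamini-Hochberg, and a probe was called at an adjusted p under 0.05. Comparisons were each FKC with control, the mean of the 4 FKC with control, the 2 Gram-negative FKC (E. tarda and V. anguillarum) with the 2 Gram-positive FKC (L. garvieae and S. iniae), any difference among the 4 FKC (moderated F test) and each pair of FKC.

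Where a probe was not well above background on arrays of the dimmer side of a comparison, or saturated on arrays of the brighter side, only a bound is given. The bound sets the mean of the brighter group, saturated spots at their value, against the mean of the dimmer group. Dim arrays count there at the higher of the probe's own value and the lowest value among probes well above background. Spots with outlier marks enter no bound unless stated. Such bounds are written as "at least N-fold". They allow for dim and saturated values alone, and not for the spread between arrays or for the slide. A p-value printed beside a bound tests the fitted difference, with dim values as they stand, and not the bound. Because no table names the probes, the rule fixed in advance names the 2 probes that rose most and the 2 that fell most in each comparison, among those called. They were ranked by fitted difference, with dim values as they stand. Ranked by fold or bound instead, a choice made after seeing the data, 28 of the 43 places went to a probe the rule names. Another 2 probes of the S. iniae comparison were named after their values were seen, because only 4 probes were called there. The groups, comparisons, tests, naming rule and most alternatives were chosen before the data were examined. Bounds for groups dim or saturated on only some arrays were chosen afterwards, as was the score with split controls. Alternatives chosen afterwards were keeping marked spots, requiring 2 unmarked arrays per compared group, and fitting each slide alone.

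The files place the samples on 2 slides. Slide 1 held the 4 controls, the 3 E. tarda samples and L. garvieae sample 1. Slide 2 held L. garvieae samples 2 and 3, the 3 S. iniae and the 3 V. anguillarum samples. Slide was tested as a term of the model and used as a block, and comparisons were repeated within each slide that held both sides. Once the slide is a block, L. garvieae is the only group that links the slides.

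For comparisons that share the 4 controls, 100 simulations of unchanged groups against those controls gave the correlation and overlap expected with no effect, and the controls were split 2 and 2 in all 6 ordered ways. Other alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, a median shift, the authors' log2 table, no filter on dim probes, a filter over all 16 arrays, eBayes with trend and robust settings, array weights, the replicate number as a block, a 2-fold minimum, fits of only the groups compared, and leaving out each array in turn. Figures and short tables were made with matplotlib 3.10.9 and pandas 2.3.3, and exact permutation tests with scipy 1.17.1.

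The procedure was tested on simulated data built from the 6450 kept probes, with 50 probes changed at each of 4 fold sizes in each FKC comparison with control. For E. tarda it recovered 49 of 50 probes changed 8-fold, 45 changed 4-fold, 29 changed 2-fold and 17 changed 1.5-fold. For S. iniae the numbers were 49, 45, 26 and 11. Calls among the unchanged probes numbered 15 for E. tarda, 12 for L. garvieae, 8 for S. iniae and 10 for V. anguillarum, out of 155, 150, 139 and 138 calls. The number of arrays limits the precision.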

Results

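The data are 16 one-colour arrays of whole kidney from Japanese flounder averaging 9.7 g, kept at 20 °C and sampled 6 hours after an intraperitoneal injection of 100 µl. In bony fish the kidney holds blood-forming and immune tissue as well as nephrons. Controls (n = 4) were taken as injected with PBS from their extraction label, although their treatment text speaks of bacterial cells suspended in PBS, and every comparison with control rests on that reading. The other groups (n = 3 each) received formalin-killed cells (FKC) of a fish pathogen. Edwardsiella tarda and Vibrio anguillarum are Gram-negative, and Lactococcus garvieae and Streptococcus iniae are Gram-positive. The stated doses differed. They were 0.263 mg or 60000000 cells of E. tarda, 1.78 mg or 43000000 cells of L. garvieae, 2.58 mg of S. iniae with no cell number given, and 73.4 µg or 50000000 cells of V. anguillarum. The comparisons ask how kidney transcripts differed after each preparation, as injected.

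Between 60.3% and 69.9% of the spots were well above background on each array (median 66.0%), and 648 to 808 spots per array were saturated. The 75th percentile of the processed intensity lay between 4971 and 6356. Each array correlated with the others of its group at a mean r of 0.971 to 0.983 across probes, which are not independent replicates. The first principal component of 5215 probes carried 30.7% of the variance and the second 12.4%. Outlier marks were tied to brightness: they fell on 0.0492% of probe values more than 1 log2 unit below the 75th percentile, on 47.9% of values 2 to 3 log2 units above it, and on 0.214% of values more than 3.5 above it, where 90.0% were saturated. Some bright probes therefore had few usable arrays in a group, and where that holds for a named probe the number is given. As a term of the model, the slide gave 0 calls in limma among 5859 probes (360 at an unadjusted p under 0.05). Its estimate rests on L. garvieae alone, with 1 array on slide 1 and 2 on slide 2. The 0 calls therefore do not show that the slides were alike.

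**Figure D1:**
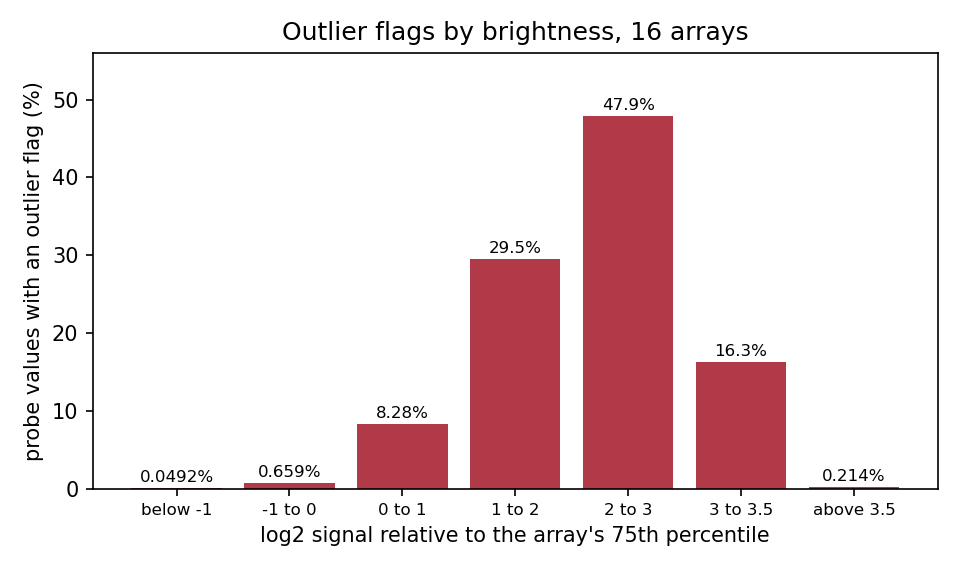
Share of probe values with an outlier mark (vertical axis, %) by brightness (horizontal axis, log2 signal relative to the array's 75th percentile), over all probes of the 16 arrays. The share peaks at 47.9% between 2 and 3 log2 units and is 0.214% above 3.5.

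After E. tarda FKC, 262 probes were higher and 138 lower than in controls, of 6158 tested. The probe AB362423 (5′-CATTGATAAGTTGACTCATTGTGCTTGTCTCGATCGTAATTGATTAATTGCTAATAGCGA-3′) was not well above background on any of the 4 control arrays (−8.24 ± 0.42 log2 relative to the 75th percentile, SD, n = 4). It rose to −0.64 ± 0.91 (SD, n = 3) in E. tarda samples, at least 65.6-fold higher (limma adjusted p = 0.000319). The probe EU224372 (5′-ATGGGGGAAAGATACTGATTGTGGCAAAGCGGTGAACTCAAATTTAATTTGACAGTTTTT-3′) rose from −7.58 ± 1.19 (SD, n = 4), with 1 of 4 controls well above background, to −0.84 ± 0.90 (SD, n = 3), at least 49.4-fold (limma adjusted p = 0.00339). Ranked by bound, the reverse-orientation probe rev_POC00077_1, with 3 of 4 controls well above background, comes first at 104-fold or more (limma adjusted p = 0.000872). The contig probe POC02860_1 fell from −4.31 ± 0.31 (SD, n = 4) to −8.50 ± 0.61 (SD, n = 3), not well above background on any E. tarda array and at least 5.34-fold lower (limma adjusted p = 0.00200). The contig probe POC01436_1 fell by 4.32 log2 units (SE 1.06, adjusted p = 0.0289). Among the called probes the median absolute difference was 1.16 log2 units, and 186 of the higher and 54 of the lower differed at least 2-fold.

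All 7 arrays of controls and E. tarda FKC lie on slide 1. With the slide as a block 271 probes were higher and 137 lower, 377 of the 400 calls being shared, and within slide 1 alone 171 were higher and 70 lower. Without control 3, 179 probes were higher and 66 lower. The number of calls was 196 without control 4, and 266, 199 and 185 without E. tarda sample 1, 2 or 3. POC01436_1 was no longer called without control 3 (adjusted p = 0.0717), control 4 (0.0717) or E. tarda sample 1 (0.0666), 2 (0.108) or 3 (0.0723). With normexp and quantile normalization 207 probes were higher and 177 lower, so the share of higher calls moved from 65.5% to 53.9%.

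Following L. garvieae FKC, 33 probes were higher and 3 lower than in controls, of 6139 tested. AB362423 reached −3.71 ± 1.21 (SD, n = 3) against −8.24 ± 0.42 (SD, n = 4), at least 7.83-fold higher (limma adjusted p = 0.0120; 5.14-fold without L. garvieae sample 2, 11.8-fold without sample 1). The reverse-orientation probe rev_POC04895_1 rose by 4.55 log2 units (SE 0.89, adjusted p = 0.0429), from −2.02 ± 1.49 (SD, n = 4) to 2.53 ± 1.73 (SD, n = 3), and by 3.84 to 5.55 when 1 array was left out. POC00193_1 fell by 0.93 (SE 0.15, adjusted p = 0.0120) and rev_POC01536_1 fell by 0.88 (SE 0.13, adjusted p = 0.0104), both below 2-fold. Of the 36 called probes, 32 were also called after E. tarda FKC in the same direction. Both comparisons use the same controls, and with these split 2 and 2 an average of 6.83 probes were called in both (0 to 20).

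The number of these calls depended on single arrays. It was 3 without L. garvieae sample 2, 9 without sample 3, 87 without sample 1, 58 without control 1 and 21 without control 4. AB362423 lost its call without sample 2 (adjusted p = 0.0825) or 3 (0.0740), POC00193_1 without sample 2 (0.0825) or 3 (0.0503), and rev_POC01536_1 without sample 2 (0.0825). For rev_POC04895_1 the adjusted p was 0.255 without sample 2, 0.151 without sample 3, 0.0765 without control 2 and 0.0888 without control 4. With 1 array left out, AB362423 still differed by 3.92 to 5.12 log2 units. POC00193_1 differed by −0.99 to −0.86 and rev_POC01536_1 by −0.96 to −0.83. A smaller group also gives a less precise test, so a lost call alone does not show that a difference rested on 1 array. L. garvieae sample 1 lies on slide 1 and the others on slide 2. A slide block gave 4 probes higher and 1 lower, 4 of these calls being shared with the unblocked fit. None of the 4 named probes was called (limma adjusted p = 0.654 for AB362423, 0.913 for rev_POC04895_1, 0.449 for POC00193_1 and 0.387 for rev_POC01536_1). The fitted difference moved from 4.52 to 3.33 log2 units for AB362423 and from 4.55 to 2.55 for rev_POC04895_1, and stayed close for POC00193_1 (−0.93 to −0.89) and rev_POC01536_1 (−0.88 to −0.84). Within slide 1, which holds 1 L. garvieae array assumed to vary like the other groups, limma called 0 probes (277 at an unadjusted p under 0.05). With normexp and quantile normalization 22 probes were higher and 8 lower, and AB362423 and rev_POC04895_1 were not called. rev_POC04895_1 also lost its call with quantile normalization, with the median shift and with no filter on dim probes.

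After S. iniae FKC, 4 probes were higher and 0 lower than in controls, of 6141 tested in limma. At an unadjusted p under 0.05 there were 540, where 307 would be expected with no effect. The contig probe rev_POC02489_1 rose by 1.14 log2 units (SE 0.15, adjusted p = 0.00732), from −5.30 ± 0.31 (SD, n = 4) to −4.16 ± 0.06 (SD, n = 3). The other calls were POC00064_1 (at least 9.86-fold, adjusted p = 0.000185, both unmarked S. iniae values saturated), POC04277_1 (3.22, SE 0.22, adjusted p = 0.00396) and POC00085_1 (1.89, SE 0.21, adjusted p = 0.0231). These 3 rested on 1, 1 and 2 unmarked control arrays and on 2, 1 and 1 unmarked S. iniae arrays. With marked spots kept POC00064_1 was at least 3.13-fold higher and the other 2 differed by 0.83 and 0.54 log2 units (adjusted p = 0.376, 0.705 and 0.699), and rev_POC02489_1 alone was called (adjusted p = 0.0237). rev_POC02489_1 and POC00085_1 were chosen after their values were seen.

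All 3 S. iniae arrays lie on slide 2, so the comparison with controls cannot be made within a slide. Only POC00064_1 was called with the slide as a block, and adjusted p was 0.0868 for POC04277_1 and 0.360 for both rev_POC02489_1 and POC00085_1. Their fitted differences stayed close, going from 3.22 to 3.02, from 1.14 to 1.22 and from 1.89 to 1.69 log2 units. There were 2 calls without control 4, 2 without S. iniae sample 1 and 7 without sample 2. rev_POC02489_1 was not called without S. iniae sample 1 (adjusted p = 0.0641), nor POC00085_1 without control 2 (0.0802) or control 4 (0.0601). Other scalings gave 10 higher and 3 lower (normexp and quantile), 6 and 2 (quantile) and 5 and 1 (median shift).

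After V. anguillarum FKC, 509 probes were higher and 520 lower than in controls, of 6096 tested. AB362423 rose to 0.47 ± 0.58 (SD, n = 3) from −8.24 ± 0.42 (SD, n = 4), at least 142-fold higher (limma adjusted p = 4.69e-05). The reverse-orientation probe rev_POC00077_1 (5′-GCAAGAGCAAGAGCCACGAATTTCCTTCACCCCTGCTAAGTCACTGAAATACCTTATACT-3′) rose from −4.97 ± 1.11 (SD, n = 4), with 3 of 4 controls well above background, to 2.53 ± 0.12 (SD, n = 3), at least 178-fold (limma adjusted p = 0.000204). POC02860_1 fell to −8.93 ± 0.17 (SD, n = 3), not well above background on any of the 3 arrays and at least 5.49-fold lower (limma adjusted p = 0.000505). POC01436_1 fell from −1.23 ± 0.44 (SD, n = 4) to −5.78 ± 3.24 (SD, n = 3), with 2 of 3 arrays well above background, at least 14.5-fold (limma adjusted p = 0.0111). Its 3 values there were −8.75, −6.25 and −2.32, so that bound holds for their mean alone: without sample 1 the probe fell by 3.06 log2 units (adjusted p = 0.0390). The bound was 8.34-fold without sample 1 and 37.9-fold without sample 3. In a fit of only these 2 groups it was not called (adjusted p = 0.0728). The median absolute difference of the called probes was 1.04 log2 units, and 342 of the higher and 199 of the lower differed at least 2-fold.

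**Figure D2:**
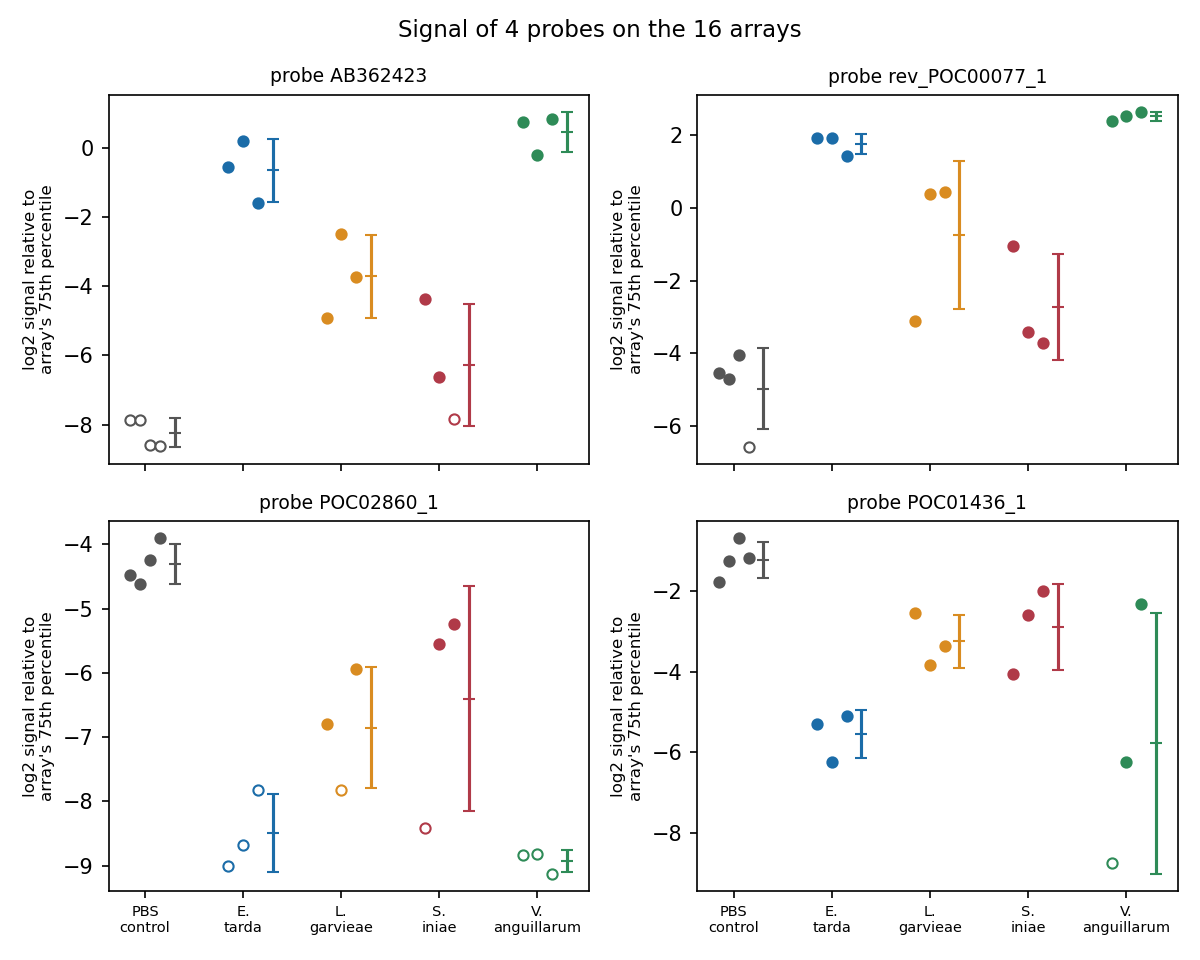
Signal of 4 named probes (vertical axes, log2 relative to the array's 75th percentile) in the 5 groups, 1 point per array, with the mean and SD of each group beside the points. Open points were not well above background: for AB362423 these were all 4 controls and 1 S. iniae array, for POC02860_1 all E. tarda and V. anguillarum arrays, 1 L. garvieae and 1 S. iniae array, for rev_POC00077_1 1 control, and for POC01436_1 1 V. anguillarum array.

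Controls lie on slide 1 and V. anguillarum samples on slide 2, so no slide holds both. A slide block gave 26 probes higher and 9 lower, while 1011 of the 1029 differences kept their direction and the median SE rose from 0.22 to 0.40 log2 units. In that fit AB362423 was still called (adjusted p = 0.0435), but rev_POC00077_1 (adjusted p = 0.225), POC02860_1 (0.199) and POC01436_1 (0.594) were not. The fitted difference moved from 7.50 to 3.97 log2 units for rev_POC00077_1, from 8.70 to 6.91 for AB362423 and from −4.55 to −3.49 for POC01436_1, and stayed close for POC02860_1 (−4.62 to −4.53). Without V. anguillarum sample 3 there were 576 calls.

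**Figure D3:**
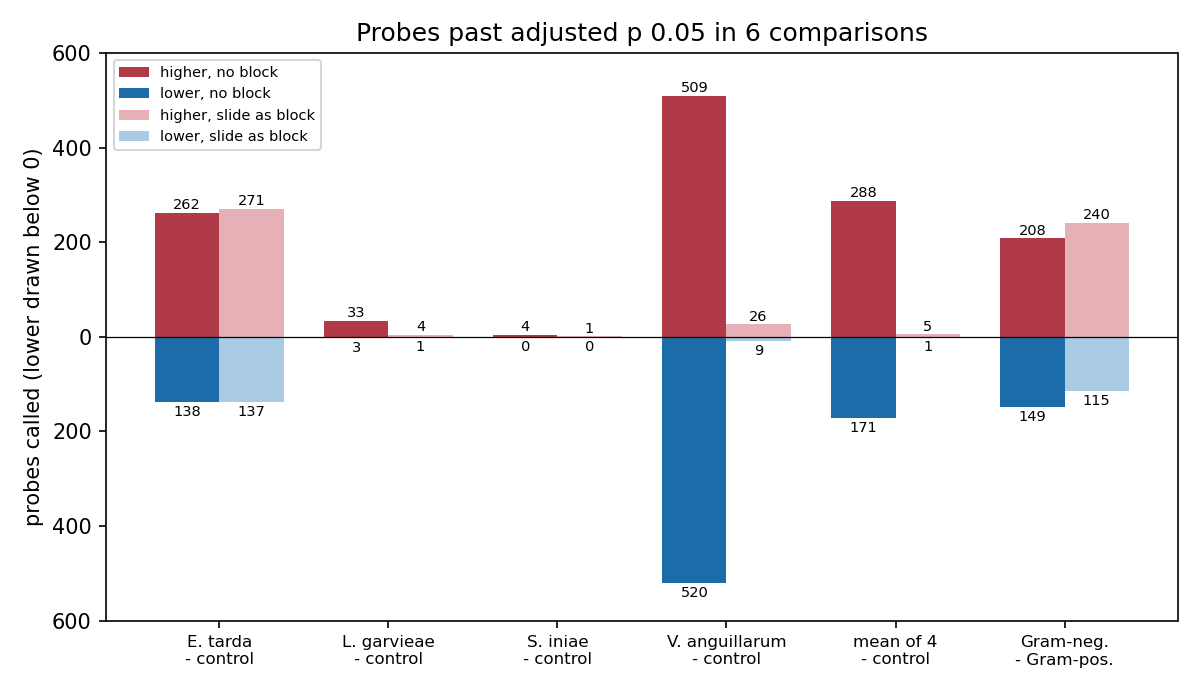
Number of probes called higher (above 0) and lower (below 0) in 6 comparisons, without a block (dark) and with the slide as a block (light). The block leaves E. tarda at 271 higher and 137 lower, and V. anguillarum at 26 higher and 9 lower.

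Averaged over the 4 FKC, 288 probes were higher and 171 lower than in controls, of 5992 tested. AB362423 averaged −2.54 in FKC samples, at least 17.6-fold above controls (limma adjusted p = 0.000227), and was well above background on 11 of 12 FKC arrays. EU224372, well above background on 1 of 4 controls, was at least 18.6-fold higher (adjusted p = 0.00251). POC02860_1, well above background on 4 of 12 FKC arrays, was at least 4.23-fold lower (adjusted p = 0.00143). POC01436_1, on 11 of 12, was at least 7.82-fold lower (adjusted p = 0.0308). A slide block gave 5 higher and 1 lower, and none of these 4 was called (adjusted p = 0.112, 0.512, 0.256 and 0.680). Their fitted differences moved from 5.69 to 4.50, from 5.32 to 3.43, from −3.36 to −3.30 and from −3.14 to −2.44 log2 units. Calls numbered 238 without control 3 and 189 without control 4. POC01436_1 lost its call without control 1 (adjusted p = 0.0604), 2 (0.0555), 3 (0.105) or 4 (0.0969) or L. garvieae sample 2 (0.0505). With normexp and quantile normalization 275 probes were higher and 282 lower.

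Probes called in the same direction for all 4 FKC numbered 4, all higher, and they are the 4 called after S. iniae FKC. The simulations of unchanged groups gave at most 0 such probes, and independent lists would share 7.18e-05. The lists are not independent, since all 4 comparisons use the same controls. POC00064_1 and POC04277_1 rested on 1 unmarked control and POC00085_1 on 2, the same ones in each comparison. Among 100 drawn splits of the samples, the real one included, the highest other count was 3. After E. tarda FKC POC00064_1 was saturated on all 3 arrays, as it was after L. garvieae and V. anguillarum FKC, against 1 unmarked control, the dimmest of the 4 (limma adjusted p = 9.95e-05, 0.000126 and 4.69e-05). With marked spots kept its control mean was 1.83 (0.38 to 2.84, n = 4), and it was at least 3.71-fold, 3.48-fold and 3.92-fold higher (adjusted p = 0.0262, 0.107 and 0.00999). In the same setting and groups, limma adjusted p was 0.0747, 0.248 and 0.0324 for POC04277_1, and 0.0115, 0.115 and 0.0115 for POC00085_1. rev_POC02489_1 rose by 1.36, 1.30 and 1.26 log2 units (SE 0.15 each, adjusted p = 0.000429, 0.00175 and 0.000239) in those 3 groups. A slide block left its E. tarda call and ended those for L. garvieae (1.35, adjusted p = 0.0641) and V. anguillarum (1.33, adjusted p = 0.0925). The count was 1 without control 4, 2 without S. iniae sample 1, 1 with the slide as a block and 1 with marked spots kept. In all, 1098 probes were called for at least 1 FKC, 763 of them for 1 alone, 303 for 2 and 28 for 3. E. tarda and V. anguillarum without the others accounted for 296.

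Between E. tarda and V. anguillarum, 215 probes were called higher in both and 117 lower in both, with 0 opposite, of 6057 tested in both. Independent lists would share 21.2 and 11.8. Their differences from control correlated at r = 0.82 across probes, against a mean of 0.42 in simulations of unchanged groups with the same controls. The covariance was 0.437 against a simulated 0.0507. With the controls split 2 and 2, r averaged 0.65 (0.63 to 0.66 over 6 splits) and 116 probes were called in both (85 to 150). E. tarda and L. garvieae had r = 0.68 (split controls 0.44), L. garvieae and V. anguillarum 0.67 (0.47), L. garvieae and S. iniae 0.60 (0.27), E. tarda and S. iniae 0.58 (0.31), and S. iniae and V. anguillarum 0.56 (0.34), with simulated means of 0.42 or 0.43. Neither the simulations nor the splits take account of the slide. A difference between slides would raise the correlations among L. garvieae, S. iniae and V. anguillarum, which lie wholly or mostly on slide 2 while all controls lie on slide 1.

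**Figure D4:**
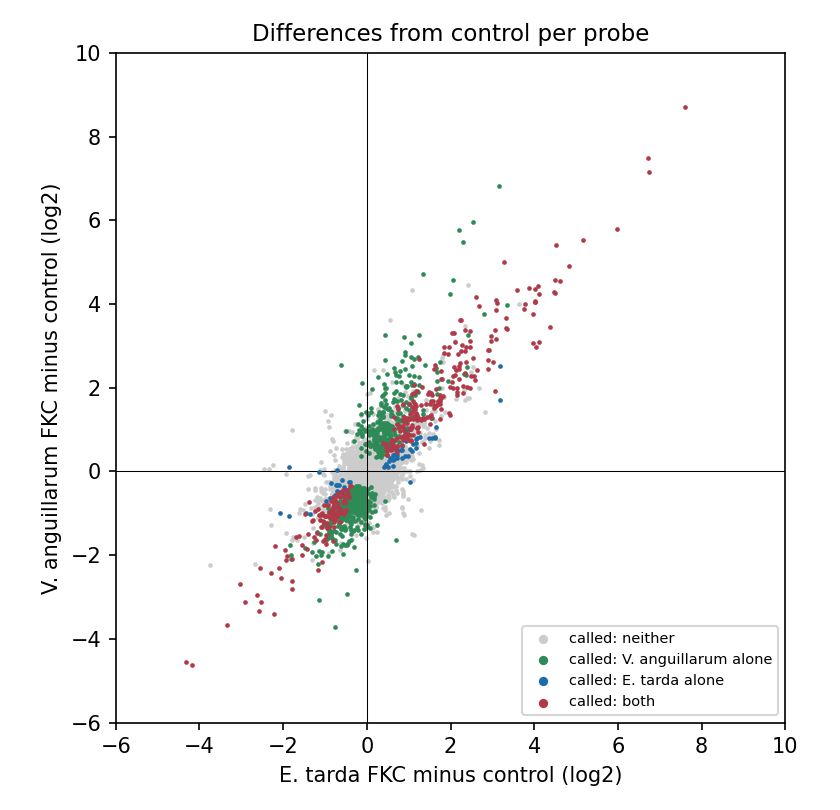
Difference from control per probe (log2) after E. tarda FKC (horizontal axis) and V. anguillarum FKC (vertical axis), coloured by the comparison in which the probe was called. The 215 probes higher in both and 117 lower in both lie along the diagonal, and no probe was called in opposite directions.

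**Figure D5:**
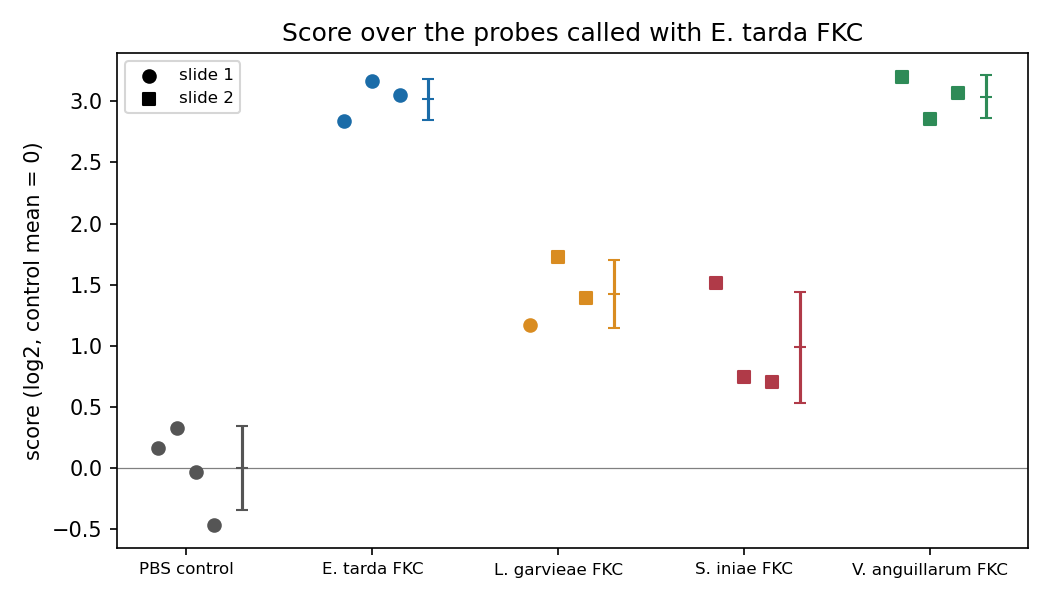
Score of the E. tarda response per array (vertical axis, log2, control mean at 0) in the 5 groups, circles for slide 1 and squares for slide 2, with the mean and SD of each group. Means were 3.02 after E. tarda FKC, 3.04 after V. anguillarum, 1.43 after L. garvieae and 0.99 after S. iniae FKC; the controls at 0 also served to choose the probes, and the score is the mean of the probes higher after E. tarda FKC minus that of the lower ones.

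The Gram-negative preparations were compared with the Gram-positive ones as injected, so bacterium, dose and Gram type vary together. In this comparison 208 probes were higher and 149 lower after Gram-negative FKC, of 6013 tested. AB362423, well above background on 5 of 6 Gram-positive arrays, was at least 27.1-fold higher (adjusted p = 0.00126), with 6 of 6 Gram-negative samples above the Gram-positive mean. AY533023 was not well above background on any of the 6 Gram-positive arrays and averaged −4.00 over the Gram-negative arrays, 5 of 6 well above background, at least 6.50-fold higher (limma adjusted p = 0.00787). Its mean was −5.72 ± 2.49 (SD, n = 3) after E. tarda FKC and −2.29 ± 2.14 (SD, n = 3) after V. anguillarum FKC, and the bound was 4.12-fold without E. tarda sample 2 and 9.96-fold without V. anguillarum sample 2. POC04479_1 was lower, with a difference of −2.24 (SE 0.32, adjusted p = 0.00224), and POC02376_1 was at least 1.65-fold lower (adjusted p = 0.00293), not well above background on any Gram-negative array.

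Blocked by slide, 240 probes were higher and 115 lower, 249 of the 357 calls being shared. Within slide 2, where V. anguillarum stands against L. garvieae and S. iniae, 94 were higher and 58 lower, and POC04479_1 was not called. Within slide 1, E. tarda against 1 L. garvieae array, limma called 0 (495 at an unadjusted p under 0.05). Calls numbered 231 without E. tarda sample 2, 213 without L. garvieae sample 1, 206 and 222 without S. iniae samples 2 and 3, and 206 and 219 without V. anguillarum samples 1 and 3.

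Across the 4 FKC groups, 217 of 6013 probes differed in the moderated F test. Blocked by slide there were 287. Slide 2 alone holds no E. tarda array and 2 L. garvieae arrays. There 100 of 5878 probes differed among L. garvieae, S. iniae and V. anguillarum FKC. Over all 4 groups without a block, the number was 123 and 127 without S. iniae samples 2 and 3, and 81 and 76 without V. anguillarum samples 1 and 3.

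S. iniae and V. anguillarum, both on slide 2, differed most among the pairs, with 150 probes higher and 266 lower after S. iniae FKC. Within slide 2 alone these were 74 and 162, and with the slide as a block 194 and 316. AB362423 was lower after S. iniae FKC, where 2 of 3 arrays were well above background, by at least 87.6-fold (adjusted p = 0.00121). AY533023 was at least 21.7-fold lower (adjusted p = 0.0104), not well above background on any S. iniae array. The bound for AY533023 was 13.9-fold without V. anguillarum sample 3 and 51.1-fold without sample 2, and that for AB362423 153-fold without S. iniae sample 1. POC00675_1 was at least 2.61-fold higher (adjusted p = 0.00403), and POC04479_1 was higher by 2.73 (SE 0.46, adjusted p = 0.00406). The number of calls was 180 and 208 without S. iniae samples 2 and 3, and 194 and 164 without V. anguillarum samples 1 and 3. AY533023 lost its call without V. anguillarum sample 1 (adjusted p = 0.0504) or 3 (0.0578).

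L. garvieae and V. anguillarum differed at 107 probes higher and 107 lower after L. garvieae FKC. AY533023 was at least 20.9-fold lower (adjusted p = 0.0120) and AB198060 at least 26.98-fold lower (adjusted p = 0.0209), both not well above background on any L. garvieae array. The sequences of these probes overlap over almost their whole length, so their results are not independent of each other. Without V. anguillarum sample 2 these bounds were 49.1-fold and 62.6-fold, and they fell as low as 13.3-fold without sample 3 and 17.3-fold without sample 1. POC05084_1 was at least 3.25-fold higher (adjusted p = 0.0168) and rev_POC00590_1 at least 1.94-fold higher (adjusted p = 0.0336). Neither was well above background on any V. anguillarum array, and rev_POC00590_1 was on 2 of 3 L. garvieae arrays. With the slide as a block 40 were higher and 54 lower, and of the 4 named probes AY533023 alone was called (adjusted p = 0.0446, against 0.0619 for POC05084_1, 0.104 for rev_POC00590_1 and 0.0643 for AB198060). The fitted differences of these 3 stayed close, at 2.79 and then 2.62, 2.66 and then 2.49, and −5.88 and then −5.86 log2 units. A fit of only these groups left 0 higher and 3 lower, and within slide 2 alone, with 2 L. garvieae arrays, 0 and 1. The number of calls was 30 without L. garvieae sample 1, and 69 and 46 without V. anguillarum samples 1 and 3. Leaving out those same 3 arrays ended the call of AY533023 (adjusted p = 0.0599, 0.0516 and 0.0550) and of AB198060 (0.0790, 0.0774 and 0.0874), as did leaving out L. garvieae sample 3 for AB198060 (0.0603). POC05084_1 lost its call without L. garvieae sample 1 (0.0770) or 3 (0.0520) or V. anguillarum sample 3 (0.0746). rev_POC00590_1 lost it without L. garvieae sample 1 (0.127) or 2 (0.0837), or V. anguillarum sample 1 (0.0522), 2 (0.0695) or 3 (0.124). The median shift gave 66 higher and 128 lower, and normexp with quantile normalization 87 and 153.

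The other pairs gave fewer calls. E. tarda against S. iniae had 30 higher and 5 lower, AB362423 being at least 40.5-fold higher after E. tarda FKC (adjusted p = 0.00979), with 2 of 3 S. iniae arrays well above background. That call was lost without E. tarda sample 2 (adjusted p = 0.0580) or S. iniae sample 2 (0.0558) or 3 (0.0668). rev_POC00077_1 was higher by 4.48 (SE 0.91, adjusted p = 0.0495), POC04479_1 lower by 2.40 (SE 0.46, adjusted p = 0.0390), and POC02376_1 at least 1.97-fold lower (adjusted p = 0.0495), not well above background on any E. tarda array. Each of these 3 lost its call without E. tarda sample 1, 2 or 3 or S. iniae sample 2 or 3 (adjusted p = 0.0793 to 0.176). The slide block also ended the calls of POC04479_1 (0.0547) and POC02376_1 (0.0783), at −3.62 and −3.49. It left those of rev_POC00077_1 and AB362423, whose fitted differences moved from 4.48 to 8.01 (adjusted p = 0.0118) and from 5.64 to 7.43 (adjusted p = 0.0274). Leaving out S. iniae sample 1 took the bound of AB362423 to 70.8-fold, and leaving out 1 array took rev_POC00077_1 as high as 5.32. The slide as a block gave 37 higher and 3 lower, and normexp with quantile normalization 35 and 20. Calls numbered 3 and 20 without E. tarda samples 2 and 3, and 73, 3 and 2 without S. iniae samples 1, 2 and 3. E. tarda against V. anguillarum had 5 higher and 16 lower. The most negative differences were those of POC02895_1 (−2.33, SE 0.36, adjusted p = 0.0259) and POC01535_1 (−2.03, SE 0.39, adjusted p = 0.0470). Both probes averaged above controls in both groups, less so after E. tarda FKC. POC02895_1 stood at −3.01 in controls, −2.13 after E. tarda FKC and 0.20 after V. anguillarum FKC. POC03136_1 was higher after E. tarda than after V. anguillarum FKC by 1.16 (SE 0.22, adjusted p = 0.0470). Both its means (−0.20 and −1.35) lay below that of controls (0.38). POC01111_1 was at least 2.70-fold higher with 2 unmarked V. anguillarum arrays and 2 of 3 E. tarda arrays saturated (adjusted p = 0.0286), and at least 2.16-fold with marked spots kept (adjusted p = 0.0773). Blocked by slide, limma called 0 there (328 at an unadjusted p under 0.05), and the fitted differences were −0.71 for POC02895_1, −0.43 for POC01535_1, 1.28 for POC03136_1 and 2.04 for POC01111_1. The number was 1, 0 and 2 without E. tarda sample 1, 2 or 3, and 1 and 0 without V. anguillarum sample 1 or 3 (774 and 558 unadjusted where it was 0). Each of these also ended the calls of all 4 named probes (adjusted p = 0.0593 to 0.189). Without V. anguillarum sample 2 there were 121 calls.

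E. tarda against L. garvieae had 3 calls. POC00710_1 was at least 9.82-fold higher after E. tarda FKC (adjusted p = 0.0139; 5.24-fold without E. tarda sample 2, 14.8-fold without sample 3), EF530037 was at least 14.9-fold higher with 1 unmarked L. garvieae array and 2 of 3 E. tarda arrays saturated (adjusted p = 0.0311), and POC00927_1 was at least 1.49-fold lower (adjusted p = 0.0106). POC00927_1 was not well above background on any E. tarda array, and was on 2 of 3 L. garvieae arrays. Its adjusted p belongs to the fitted difference of −2.12 log2 units (SE 0.26), not to the bound. With the slide as a block limma called 0 (536 at an unadjusted p under 0.05). Within slide 1, which holds 1 L. garvieae array, all 3 differences kept their direction. Blocked, the fitted differences were 4.39 log2 units for POC00710_1, 3.89 for EF530037 and −2.41 for POC00927_1, against 4.34, 3.89 and −2.12. Calls also numbered 0 without E. tarda sample 1 or L. garvieae sample 1 or 3 (592, 460 and 470 unadjusted), 7 without E. tarda sample 3 and 6 without L. garvieae sample 2. The calls ended without E. tarda sample 1 (adjusted p = 0.0526 for POC00710_1, 0.137 for EF530037 and 0.0526 for POC00927_1). They also ended without L. garvieae sample 3 (0.0717, 0.0533 and 0.0533), and for POC00710_1 and POC00927_1 without L. garvieae sample 1 (0.106 and 0.102). EF530037 lost its call without E. tarda sample 2 as well (adjusted p = 0.142), and with marked spots kept it was at least 5.81-fold higher (adjusted p = 0.121). L. garvieae against S. iniae had 2 calls, POC01490_1 (at least 8.42-fold higher) and POC01919_1 (at least 4.28-fold higher), each with adjusted p = 0.0135, 1 unmarked S. iniae array, and both unmarked L. garvieae values saturated. Neither was called with marked spots kept (at least 2.76-fold and 2.22-fold, adjusted p = 0.448 for both), which left limma 0 calls (526 unadjusted). The count was 2 within slide 2, 10 with the slide as a block, 6 without L. garvieae sample 1, and 0 without L. garvieae sample 2 or 3 or S. iniae sample 2 (334, 431 and 493 unadjusted). Leaving out E. tarda sample 1 or 3, or any V. anguillarum sample, which add to the error estimate alone, also gave 0 (459, 487, 469, 506 and 479 unadjusted).

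Probes named by an accession were set against the contig probes as a group. After E. tarda FKC 22 of 339 accession probes were higher (6.49%) and 240 of 5819 others (4.12%). After L. garvieae FKC the numbers were 6 of 338 (1.78%) and 27 of 5801 (0.465%), and after V. anguillarum FKC 38 of 333 (11.4%) and 471 of 5763 (8.17%). No difference passed Fisher's exact test after adjustment over 10 two-sided tests, the lowest adjusted p being 0.0834 for L. garvieae.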

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

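The tests of outlier marks, slides, spread between arrays and probe orientation below were chosen after the results they concern were seen; the counts of other splits were planned.

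Among the 4 controls, AY533023 stood at −6.54 log2 relative to the 75th percentile in control 4, against −8.99 to −8.67 in the others. POC05084_1 stood at −4.96 in control 1, against −6.15 to −6.07 in the others. Of 31 control measures tested, 2 had a gap, as a share of the group's range, past Dixon's 95% critical value for 4 samples, and chance gives about 1 in 20. AY533023 was not well above background on any control array.

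Tests of the difference itself separated the preparations at 217 probes among the 4 FKC and at 357 probes between Gram-negative and Gram-positive FKC. Between pairs they called 3 probes for E. tarda and L. garvieae, 35 for E. tarda and S. iniae, and 21 for E. tarda and V. anguillarum. L. garvieae and S. iniae differed at 2, L. garvieae and V. anguillarum at 214, and S. iniae and V. anguillarum at 416.

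Other splits of the same samples were fitted the same way. For E. tarda against controls 1 of 35 splits, the real one, gave as many calls (400, highest other 167). The same held for L. garvieae (1 of 35, 36 against 21) and V. anguillarum (1 of 35, 1029 against 381). Each share is under 0.05 and argues against chance, but it is the smallest these splits allow. Probes were filtered by the real groups, which can favour the real split, so chance is not excluded. For L. garvieae, 3 calls remained without sample 2. These splits ignore the slide and say nothing against it. The V. anguillarum split is slide 1 against slide 2, and the slide block gave 35 calls there, 34 of them shared with the unblocked fit. For L. garvieae, with 2 of its 3 arrays on slide 2, it gave 5, of which 4 were shared. For S. iniae 5 of 35 splits gave as many (4, highest other 7), so they do not argue against chance. In 100 drawn splits 1 gave as many for the mean of the 4 FKC (459, highest other 45), for all 4 FKC together (4 against 3), for Gram type (357 against 22), for any difference among the FKC (217 against 113) and for the 6 pairs in sum (691 against 443). For Gram type the draws shuffled single samples across the 4 FKC groups. They test whether the preparations differ, and cannot tell Gram type from other pairings of the bacteria. Each pair alone has 10 splits, too few for a share under 0.05. Real counts and highest others were 3 and 2 for E. tarda and L. garvieae, 35 and 2 for E. tarda and S. iniae, and 21 and 2 for E. tarda and V. anguillarum, with 1 of 10 splits as large in each. They were 2 and 6 for L. garvieae and S. iniae (4 of 10), 214 and 2 for L. garvieae and V. anguillarum (1 of 10), and 416 and 4 for S. iniae and V. anguillarum (1 of 10).

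Outlier marks removed many bright values, which may have lifted the differences of bright probes by leaving the dimmer controls. In 39 probes called higher with 1 to 3 unmarked controls, marked control values exceeded unmarked ones by a median of 0.374 log2 units (bootstrap 0.203 to 0.468), and 30 of 39 went that way. The 39 probes were picked for a call against their unmarked controls, which favours low unmarked values. Marks that fell at random could therefore give higher marked values too. The bootstrap drew probes measured on the same 4 controls, so its interval does not measure the spread between samples. A removal of true values and a removal of faulty ones cannot be told apart here either, because both predict higher marked values. With marked spots kept, 1 of the 4 S. iniae calls remained. No biological explanation of the marks was tested.

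E. tarda and V. anguillarum gave 400 and 1029 calls against controls, L. garvieae and S. iniae 36 and 4. A difference between slides as the whole cause is argued against by 236 calls between S. iniae and V. anguillarum within slide 2. Over all kept probes, a larger spread between the arrays of L. garvieae and S. iniae is argued against. The higher of their median SDs was 1.06 times the lower of those of E. tarda and V. anguillarum. That ratio does not speak for the called probes alone, where named probes went both ways. For rev_POC00077_1 the SDs were 2.03 and 1.46 after L. garvieae and S. iniae FKC, against 0.28 and 0.12 after E. tarda and V. anguillarum FKC. For POC01436_1 they were 0.65 and 1.06 against 0.60 and 3.24. A larger spread in the called probes stays open. The bacterium, the Gram type and the dose differ together and stay open as untested. The share of the V. anguillarum calls that rests on the slide also stays open. The slide block gave 35 calls, 34 of them among the 1029, but it also raised the median SE from 0.22 to 0.40 log2 units. With it, 1011 of the 1029 differences kept their direction.

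Probes in both orientations of a contig changed together, with r across contigs of 0.53 for E. tarda (1761 pairs), 0.55 for V. anguillarum (1719 pairs), 0.34 for L. garvieae (1751 pairs) and 0.29 for S. iniae (1752 pairs). Shifts that follow brightness are argued against by reverse probes of other contigs matched for brightness, whose highest r for V. anguillarum was 0.0850 in 1000 pairings. The dimmer probe could read the same labelled RNA as the brighter one, or both strands may change. Where the brighter probe was called for V. anguillarum, the dimmer showed a median of 0.611 of its log2 difference (bootstrap 0.489 to 0.714, 140 probes). That value cannot tell these apart, and no biological explanation was tested.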

How the results depend on the processing

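Signal over background limits what can be tested, since 6450 of 9877 probes were kept. No gene list had members on the array, so the planned tests of 25 gene lists and of cell type markers could not be run. The 45 named results gave 921 values under the alternatives, of which 692 stayed called, 229 kept their direction without a call and 0 reversed. Most named results were picked as the largest called differences in these same data, and the alternatives refit the same arrays. The 0 reversals therefore say little about what other samples would show. Calls ended for 28 of 45 in fits of only the groups compared, for 26 of 45 with the slide as a block, for 26 of 45 without some single array, and for 11 of the 15 with a value in slide 1 alone. Calls also ended for 19 of 43 with the replicate number as a block and control 4 left out, and for 13 of 45 with no filter on dim probes. Where a count moved, the cause was not tested, except that fits of fewer arrays hold fewer samples.

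Arrays with the same number showed no general pairing: 8 of 30 same-numbered pairs had r over 0.1 (−0.17 to 0.52), and 7 of 15 arrays correlated best with their own number. Some arrays numbered 2 did vary together: r was 0.52 for control and E. tarda, 0.26 for E. tarda and S. iniae, and 0.20 for control and S. iniae. Pairs of number 2 that include L. garvieae or V. anguillarum had negative r. With the replicate number as a block and control 4 left out, calls numbered 161 for E. tarda, 7 for L. garvieae, 1 for S. iniae, 611 for V. anguillarum, 144 for the mean of the FKC, 133 for any difference among the FKC and 1 for all 4 FKC together. With the slide as a block there were 5 for L. garvieae, 1 for S. iniae, 35 for V. anguillarum, 6 for the mean of the FKC and 1 for all 4 together.

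Fits of only the groups compared gave 241 calls for E. tarda, 1 for L. garvieae, 0 for S. iniae in limma (488 unadjusted), 127 for any difference, 171 for the 6 pairs and 0 for all 4 together. A 2-fold minimum left 240 for E. tarda, 541 for V. anguillarum, 197 for the mean, 149 for Gram type and 451 for the 6 pairs. Array weights gave 63 for L. garvieae, 8 for S. iniae, 794 for the mean, 544 for any difference and 1268 for the 6 pairs. The median shift gave 23 and no filter on dim probes 22 for L. garvieae. For S. iniae, normexp gave 13, quantile normalization 8 and the authors' values 1, and the authors' values gave 1 for all 4 together.

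Chosen after seeing the data, slide 1 alone gave 241 for E. tarda and, in limma, 0 for L. garvieae (277 unadjusted) and 0 for Gram type (495 unadjusted). Slide 2 alone, which holds no E. tarda array, gave 152 for Gram type and 100 for any difference among the FKC on it. Keeping marked spots, or requiring 2 unmarked arrays per compared group, gave 1 for S. iniae and 1 for all 4 together.

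Leaving out 1 array at a time, calls ranged from 185 to 470 for E. tarda, 3 to 87 for L. garvieae, 2 to 7 for S. iniae, 576 to 1112 for V. anguillarum and 189 to 520 for the mean of the FKC. They ranged from 206 to 410 for Gram type, 76 to 259 for any difference, 240 to 874 for the 6 pairs and 1 to 6 for all 4 together.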

Other observations

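A score of the E. tarda response was taken per array as the mean log2 signal of the 262 probes higher after E. tarda FKC minus the mean of the 138 lower ones, relative to the control mean. It was 0 ± 0.34 (SD, n = 4) in controls and 3.02 ± 0.17 (SD, n = 3) after E. tarda FKC, where the probes were chosen. It was 3.04 ± 0.17 (SD, n = 3) after V. anguillarum FKC, 1.43 ± 0.28 (SD, n = 3) after L. garvieae FKC and 0.99 ± 0.45 (SD, n = 3) after S. iniae FKC. The probes were chosen for differing from these same controls, which also set the 0. Chosen after the scores were seen, 6 further scores took their probes from 2 controls against E. tarda and set the other 2 controls at 0. The controls used in the choice then averaged −0.36 (−0.90 to 0.29), V. anguillarum 3.59 (2.52 to 4.82), L. garvieae 1.65 (1.04 to 2.40) and S. iniae 1.06 (0.63 to 1.62). Between groups not used to choose the probes, scores differed by −1.61 between L. garvieae and V. anguillarum (exact permutation test on both sides, p = 0.1, adjusted 0.15), by −2.05 between S. iniae and V. anguillarum (exact p = 0.1, adjusted 0.15) and by 0.44 between L. garvieae and S. iniae (exact p = 0.3). With 3 samples against 3, the smallest p these tests allow is 0.1.

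Contig probes lie on the array in both orientations, 4725 pairs in all, of which 17 are exact reverse complements. The forward probe was brighter by over 1 log2 unit in 3370 pairs, the reverse in 820, and 535 lay within 1 unit. Both were well above background on all 16 arrays in 1239 pairs. After E. tarda FKC both probes were called higher in 35 contigs and both lower in 3, with 0 in opposite directions, where independent calls would give 3.35 and 0.181. After V. anguillarum FKC the numbers were 71 and 31, with 2 opposite, against 12.6 and 5.38. Of the 4727 forward probes 3683 were kept (77.9%), of the 4710 reverse probes 2413 (51.2%), and of the 440 named by an accession 354 (80.5%).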
